A study of Mus musculus with 2 samples.

How the data were processed

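The data were gene-level RNA-seq values of 2 mouse oocyte libraries that form 1 group. The sample titles call the cells small oocytes in culture with external pressure. The oocytes came from embryonic ovaries of female mice kept in culture at 33.3 kPa of added pressure, and were sorted on a CFP reporter of Stella (Dppa3). Per the labels' protocols, polyadenylated RNA was captured on magnetic beads, made into strand-specific libraries and amplified by 12 cycles of PCR. Per the submitters' processing notes, the tools were fastp 0.20.0 (read trimming and filtering), STAR 2.7.7a (alignment) and RSEM (estimation of counts, version not given in the sources used here), and the genome build was GRCm38. The annotation release, the program settings and the sequencing depth in raw reads are not given in the sources used here. The deposited values are expected counts per gene: RSEM assigns a read that matches several genes in fractions, so the values need not be whole, and 7.08% and 6.97% of the table's genes in replicates 1 and 2 were not whole. The values are scaled neither for depth nor for gene length.

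The table held 53832 genes. A further 21 columns of per-sample values match no sample of this series and were not used. Genes were matched by Ensembl ID to GENCODE release M21 for GRCm38. Of the 53832 IDs, 53579 matched and 253 did not, and those without a match held 0.0127% and 0.0102% of the counts. Coordinates are 1-based positions on GRCm38. The 2 symbols that stood on 2 rows each, Ddit3 and Aldoa, were taken from their protein-coding ID.

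The level of a gene was its expected count divided by the length of its merged exons in kilobases and rescaled within the library to a fixed sum, which gives TPM. The log scale was log2(TPM + 1), which understates ratios of low genes. A gene counted as expressed at a TPM of at least 1 in both libraries. For a gene list, the median of log2(TPM + 1) over all measured members was taken per library and for the mean of both libraries, and its place was given among 10000 random lists of the same size drawn from protein-coding genes. This place describes the 2 libraries and carries no p-value, since genes are not replicates. Errors are SDs over the 2 libraries. Shares of counts carry exact Clopper-Pearson 95% intervals. The floor, the level that a count of 3 would give, was 0.598 CPM (counts scaled to the library total alone) in replicate 1 and 0.569 CPM in replicate 2. Intervals and floors cover counting error only, since reads copied by PCR without molecular identifiers are not independent molecules.

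With 1 group there is no treated-against-untreated comparison, and with 2 libraries against 2 an exact permutation test could at best have given a two-sided p of 0.333. The comparisons were therefore made within each library, between gene lists, and between the 2 libraries. For the last, expected counts were rounded to whole numbers, genes were kept by the edgeR function filterByExpr, and each gene's counts were set against the effective library sizes (TMM scaling) in a two-sided exact binomial test with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and a ratio of at least 2-fold. Log2 ratios used a prior count of 0.5, and their SEs come from counting noise alone. A list's median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 bins. These tests compare 2 libraries, not conditions. The spread between libraries was described with the common biological coefficient of variation (BCV) of edgeR.

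The 27 gene lists, 2 lists taken by name pattern (mitochondrially encoded and cytosolic ribosomal protein genes), the tests and the alternatives were fixed before the data were examined, apart from 3 added lists and 2 added alternatives named below. The list of Y-linked genes was not analysed here. The genes named in the text follow a rule set at the same time: the 10 most abundant genes that are not mitochondrially encoded, 33 genes fixed by name, the 2 highest and 2 lowest members of each list, and the 5 largest ratios each way among called genes with a mean of at least 10 CPM. Some genes that this rule names are not reported here. Other names are marked as chosen after their values were seen, or serve as list members beside their list. Maternal gene families, the piRNA pathway, and TGF-beta family receptors with Smads were added as lists after the fixed lists' levels had been seen and before their own values were.

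The alternatives were CPM without length scaling, a pseudocount of 0.1, TMM or DESeq2 size factors, totals without mitochondrial genes, expressed genes as the background of random lists, an expression threshold of 5, no filter on low counts, no fold minimum, a negative binomial exact test with a preset BCV of 0.1, and each library left out. The length of the longest transcript, and counts of mitochondrial genes summed with their near-identical copies on chromosome 1, were added after the data had been seen. Copies were found with blastn as chromosome 1 genes of at least 95% identity over at least 50% of their length. The procedure was tested on simulated libraries drawn from the real means and totals. For the binomial test they held counting noise only. In that test of replicate 2 against replicate 1, 81% of 100 genes changed 2-fold (95 of which passed the filter) and 92% of 100 genes changed 4-fold (93 of which passed) had an adjusted p under 0.05, as did 0.0658% of 12154 unchanged genes. In separate simulated libraries with added variation, a BCV of 0.15 was estimated as 0.149. Software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.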

Results

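Polyadenylated RNA was sequenced from mouse oocytes, called small oocytes in the sample titles, of 1 group with 2 libraries, replicates 1 and 2. Ovaries from female embryos had been cultured at 33.3 kPa of added pressure, and cells with a CFP reporter of Stella (Dppa3), a gene of germ cells and oocytes, had been sorted from them. The series is about mechanical stress and the dormancy of oocytes. The libraries held 5019462 and 5274338 expected counts. Counts above 0 were found for 19241 genes in replicate 1 and 19210 in replicate 2, and 13787 genes, 11617 of them protein-coding, reached a TPM of at least 1 in both. Both libraries come from pressure-treated cultures, so the values describe small oocytes under pressure, and no effect of pressure is measured. Values are means ± SD with n = 2 unless 2 values are given, which are then those of replicates 1 and 2.

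Gene levels in the 2 libraries lay close together. Over 12182 genes with enough counts, Pearson's r of log2(CPM + 1) was 0.989 and Spearman's rho was 0.991, across genes, which are not independent replicates. The BCV was 7.31%. The counts differed by more than sampling noise, with a chi-square of 3.55 per degree of freedom, so they are not the same library deposited under 2 names; this does not show that the samples were biologically separate. Nothing in the labels says that they came from separate cultures or animals, and the spread between them may be technical.

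The first comparison asks how far the sorted cells carried transcripts of oocytes and of other ovarian cells. Germ cell markers stood at a median TPM of 256, and 11 of 12 were expressed. Among them Ybx2, a protein that binds and stores maternal mRNA, had a TPM of 1305 and 1302, and Gtsf1, a partner of the piRNA machinery, stood at 864 ± 4.84. The RNA helicase Ddx4 (ENSMUSG00000021758, chromosome 13, 112598333 to 112652475) stood at 255 ± 18.7, the RNA-binding protein Dazl at 275 and 247 and the receptor Kit (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722) at 380 ± 19.8. At the low end were Dnd1 at 17.7 ± 2.81 and Nanos3, a factor of early germ cells, with a count of 0 in both libraries, which allows up to 0.598 and 0.569 CPM. Dppa3 itself, at 6594 ± 124, was the gene of the sorting reporter and its level is no finding.

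Markers of other cell types were near the floor. Of 66 markers in 7 lists, 12 were expressed and 3 reached a TPM of 5 in both libraries. All 66 together held 490 and 451 counts, or 0.00976% and 0.00855% of each library. Granulosa markers held 0.00207% of the counts in replicate 1 (95% interval 0.00169 to 0.00251%) and 0.00144% in replicate 2 (0.00114 to 0.00180%), against 0.491% (0.485 to 0.497%) and 0.511% (0.505 to 0.517%) for germ cell markers. The granulosa regulator Foxl2 had 10 and 5 counts, the anti-Müllerian hormone receptor Amhr2 17 and 3, Nr0b1 8 and 7, Lgr5 1 and 0, and Fshr, the receptor of follicle-stimulating hormone, 0 and 0. The 3 markers at a TPM of 5 or more were the smooth muscle myosin Myh11 at 10.6 ± 2.88, the surface epithelium marker Lgals7 at 14.7 ± 2.13 and the stroma marker Mfap4 at 9.31 ± 0.46.

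Of the other stroma markers, the collagen gene Col1a1 stood at 1.81 ± 0.685, Pdgfra had 1 and 2 counts and Tcf21 none. Of the surface epithelium, Krt8 had 17 and 10 counts, Krt7 6 and 3, and Msln 1 and 0. The endothelial marker Pecam1 stood at 2.79 ± 0.785 and Tek at 1.08 ± 0.312, while Emcn and Esam had 0 counts. The perivascular genes Acta2, Pdgfrb and Cspg4 had 10 and 0, 3 and 0, and 1 and 2 counts. The leukocyte gene Ptprc, Adgre1 and Tyrobp had 0 counts, and Lyz2 had 0 and 1. Of the erythroid genes, Hbb-bs had 4 and 5 counts, Hba-a1 had 2 and 1, and Hbb-y and Slc4a1 had 0.

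On the log2(TPM + 1) scale, the germ cell median lay above that of granulosa markers by 7.13 ± 0.13, stroma markers by 7.38 ± 0.16, surface epithelium by 6.99 ± 0.29, endothelium by 7.66 ± 0.25 and perivascular cells by 7.53 ± 0.50. Each of these differences was positive in both libraries and far larger than its SD. The medians of immune and erythroid markers were 0, so no fold is given for them. The exact size depends on the pseudocount, since the lower lists lie near the floor.

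**Figure D1:**
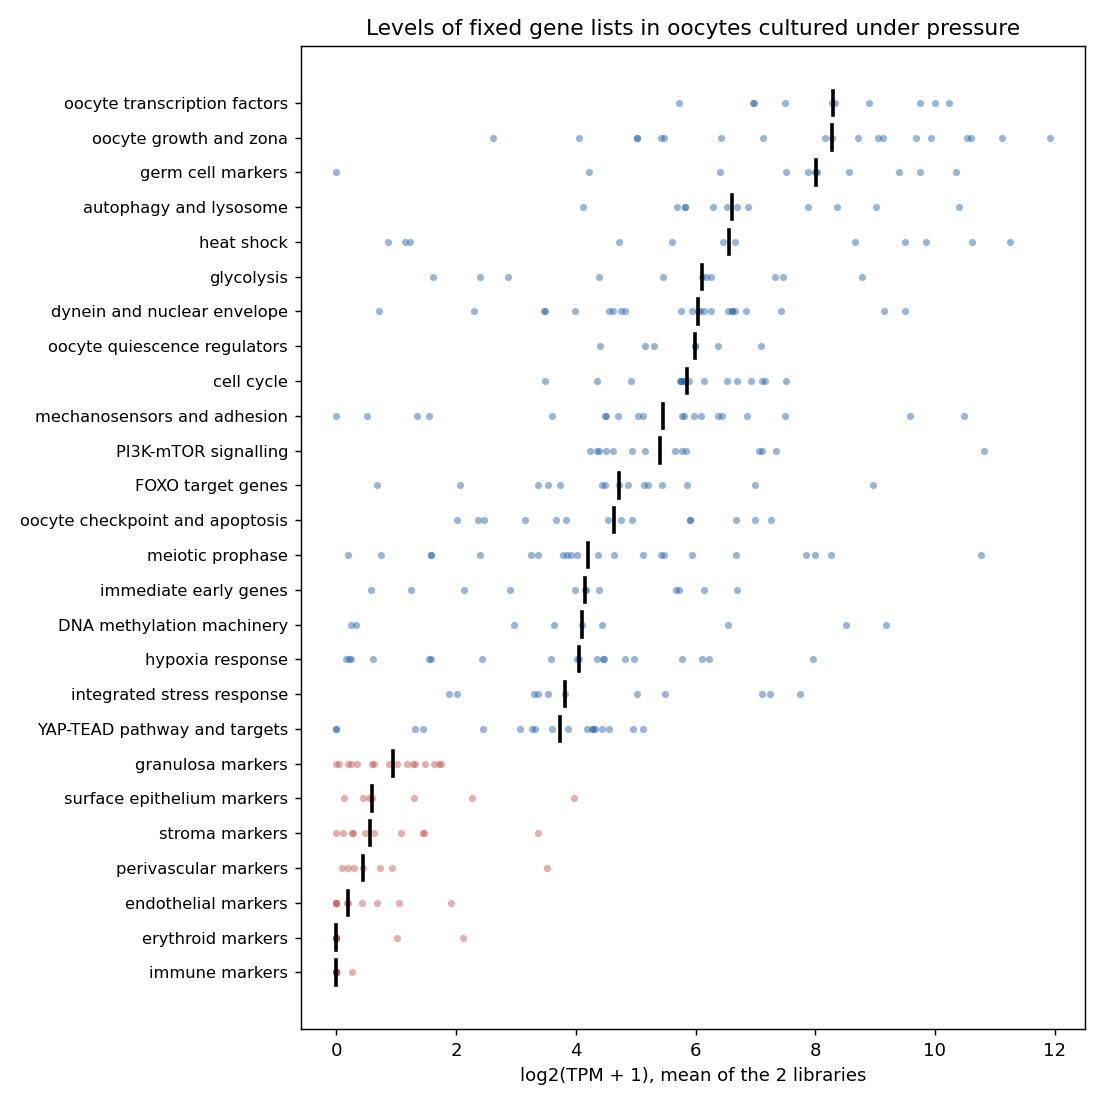
Levels of the fixed gene lists. The x axis is log2(TPM + 1) as the mean of the 2 libraries, each point is 1 gene, black bars are list medians, blue marks germ line and general programmes, and red marks other cell types, whose 7 medians are all below 1.

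The next comparison asks in which state the oocytes were, as the dormancy in the study's title concerns. Genes of oocyte transcription, of growth and of quiescence were all present in the RNA of the sorted cells, which does not show that the same cells expressed them. All 10 genes of the list of oocyte transcription factors were expressed, at a median TPM of 314. The list also holds Sub1 at 475 ± 32.4, Stat3 at 179 ± 4.98 and Dynll1, a dynein light chain and not a transcription factor, at 321 ± 0.944. Sohlh1 (ENSMUSG00000059625, chromosome 2, 25842995 to 25847248) stood at 1201 ± 19.1, Nobox (ENSMUSG00000029736, chromosome 6, 43303674 to 43309554) at 1030 ± 64.6 and Figla, which drives zona pellucida genes, at 860 ± 41.0. Lhx8 stood at 309 ± 14.4, Sohlh2 at 126 ± 12.7, Tbpl2 at 124 ± 21.1 and Taf4b at 51.7 ± 2.58.

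The 19 genes of oocyte growth and the zona pellucida were all expressed, at a median TPM of 308. Padi6, needed for the cytoplasmic lattices of the egg, stood at 3903 ± 690. The zona genes Zp2 (ENSMUSG00000030911, chromosome 7, 120126772 to 120145291), Zp3 and Zp1 stood at 2265 ± 555, 1576 ± 305 and 571 ± 141. The growth factor Gdf9 stood at 423 ± 76.4, while its paralogue Bmp15 stood at 15.7 ± 1.34 and Oosp1 at 5.24 ± 1.51.

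All 7 quiescence regulators were expressed, at a median TPM of 62.5. Foxo3 (ENSMUSG00000048756, chromosome 10, 42181841 to 42276755), the transcription factor that holds primordial follicles dormant, stood at 136 ± 8.18, and its relative Foxo1 at 20.1 ± 0.406. Tsc2 stood at 81.7 ± 6.85, Tsc1 at 34.4 ± 0.557 and the kinase inhibitor Cdkn1b at 62.9 ± 3.02. These are RNA levels and do not show where the FOXO3 protein was.

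Of 22 genes of meiotic prophase, 20 were expressed, at a median TPM of 17.3. The axis protein Sycp3 (ENSMUSG00000020059, chromosome 10, 88459569 to 88473236) stood at 1744 ± 64.6 and the cohesin Smc1b at 305 ± 8.92. Stra8, which starts meiosis, had 1 and 0 counts, and Rec8 had 3 and 4. The median of the growth list lay above that of the meiotic list by 4.12 ± 0.33 on the log2 scale, in both libraries, and above that of the quiescence list by 2.44 ± 0.56, with 2.05 in replicate 1 and 2.83 in replicate 2. Both differences depended on length scaling. With CPM in place of TPM, the lead over the meiotic list was 2.40, and the difference from the quiescence list was -0.10, so no order of those 2 lists is read from it.

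Signalling genes downstream of growth factors were present at moderate levels. All 14 PI3K-mTOR genes were expressed, at a median TPM of 41.4, from Rps6 at 1813 ± 82.6 and Eif4ebp1 at 162 ± 0.356 to Rptor at 19.3 ± 0.610 and Rps6kb1 at 17.9 ± 2.44. Of 15 FOXO target genes, 14 were expressed, at a median of 25.5. Txnip, an inhibitor of thioredoxin, stood at 501 ± 37.4 and Bnip3 at 126 ± 3.69, against 3.22 ± 0.393 for Bcl6 and 0.613 ± 0.189 for the ubiquitin ligase gene Fbxo32. The median of the PI3K-mTOR list lay above 99.7% of random lists of protein-coding genes and that of the FOXO targets above 97.8%, but among expressed genes these places were 89.6% and 55.1%.

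Of 19 hypoxia response genes, 15 were expressed, at a median TPM of 15.6. The glycolytic kinase Pgk1 stood at 249 ± 9.62 and the transcription factor Hif1a at 73.5 ± 1.76, whereas Adm and Car9, both strongly hypoxia-inducible, had 0 and 1 counts each. All 11 glycolysis genes were expressed, at a median of 68.1, with Pkm at 440 ± 27.4 and Aldoa at 176 ± 11.1 above Hk1 at 4.28 ± 0.779 and Pfkp at 2.05 ± 0.0944. The hypoxia median lay above 93.2% of random lists of protein-coding genes and the glycolysis median above 99.9%. Among expressed genes, a background without unexpressed genes, these places were 13.4% and 98.3%.

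Genes that sense or transmit force were expressed unevenly. Of 20 mechanosensor and adhesion genes, 18 were expressed, at a median TPM of 42.7. The actins Actg1 and Actb led with 1426 ± 73.3 and 769 ± 61.4. The pressure-gated channel Piezo1 had 7 and 8 counts and Piezo2 had 0. Of 18 genes of the YAP-TEAD pathway and its targets, 16 were expressed, at a median of 12.3. Yap1 stood at 19.1 ± 0.179 and its paralogue Wwtr1 at 18.4 ± 0.412. The kinase Stk3 stood at 33.7 ± 2.16. The YAP targets Ccn1 (older symbol Cyr61) and Ccn2 (Ctgf) stood at 31.2 ± 11.8 and 4.59 ± 1.53, while Ankrd1 and Tead4 had 0 counts. Of 23 dynein and nuclear envelope genes, 22 were expressed, at a median of 64.7, led by the dynein light chains Dynll2 at 725 ± 9.53 and Dynlrb1 at 569 ± 14.2, with Syne1 at 3.92 ± 0.261 and Dync1i1 at 0.636 ± 0.0172 at the low end. Among random lists of protein-coding genes, the YAP-TEAD median lay above 89.4%, the mechanosensor median above 99.97% and the dynein and nuclear envelope median above 100%. Among expressed genes these places were 5.16%, 94.1% and 99.8%. That background holds no unexpressed genes, while the lists keep theirs, so a low place there does not show an unusually low pathway.

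Cytosolic HSP90 chaperones were the most abundant of the heat shock genes. Of 12 heat shock genes, 9 were expressed, at a median TPM of 93.7. Hsp90ab1 stood at 2438 ± 25.0 and Hsp90aa1 at 1566 ± 47.5, while Hspa1a had 3.16 and 5.67 counts and Hspb1 7 and 0. Hspa1a has a near-identical paralogue, Hspa1b, so its counts are uncertain. All 11 genes of the integrated stress response were expressed, at a median of 13.1, with the endoplasmic reticulum chaperone Hspa5 at 212 ± 7.83 and Phgdh at 151 ± 10.5 above Trib3 at 3.08 ± 0.650 and Atf3 at 2.93 ± 1.94. Of 12 immediate early genes, 11 were expressed, at a median of 16.9, with Ier2 at 102 ± 7.51 and Jund at 70.2 ± 9.67, and with Fosl1 and Myc at 4 and 6 and at 4 and 1 counts.

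All 14 oocyte checkpoint and apoptosis genes were expressed, at a median TPM of 24.0, with the survival factor Mcl1 at 152 ± 13.2 and its opponent Bax at 128 ± 18.1 above Bak1 at 4.27 ± 1.45. All 16 cell cycle genes were expressed, at a median of 56.8, with Ccnb2 at 182 ± 3.86 and Pcna at 143 ± 6.84 above Aurkb at 19.5 ± 1.11 and Top2a at 10.2 ± 0.631. All 12 autophagy and lysosome genes were expressed, at a median of 96.3, with Lamp1 at 1355 ± 15.9 and Ctsd at 518 ± 26.8 above Gabarapl1 at 50.7 ± 7.01 and Atg7 at 16.5 ± 3.07. Of 9 genes of DNA methylation, 7 were expressed, at a median of 16.3. The histone demethylase Kdm1b stood at 583 ± 14.3 and Uhrf1 at 364 ± 43.6, whereas Tet1 had 8 and 6 counts and Dnmt3l, needed for imprints set in growing oocytes, had 2 and 0.

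The most abundant genes that are not mitochondrially encoded were Gm28661 at 17023 ± 2289, Gm10925 at 12632 ± 4182 and Gm28437 at 12573 ± 3922, followed by the elongation factor Eef1a1 at 8123 ± 383, Dppa3, Gm29216 at 4975 ± 992, Rplp1 at 4610 ± 169, the ubiquitin hydrolase Uchl1 at 4359 ± 75.9, Rps15 at 3909 ± 256 and Padi6. The 4 Gm genes are pseudogenes on chromosome 1, copies of mt-Co2, mt-Atp6, mt-Co3 and mt-Co1 with 99.8 to 100% identity, and how many of their counts are mitochondrial is uncertain. The 13 mitochondrially encoded protein genes had a median TPM of 5778, from mt-Co1 at 21128 ± 1528 and mt-Atp6 at 16885 ± 3213 to mt-Nd5 at 2763 ± 418 and mt-Nd6 at 54.2 ± 5.33. The levels of mt-Co1, mt-Atp6, mt-Co2 and mt-Co3 are uncertain too, as their reads may be shared with the copies. The order of the genes and their median are uncertain with them. The mitochondrial chromosome held 3.44% and 3.47% of the counts, and 4.44% and 4.69% together with the copies. Of 80 cytosolic ribosomal protein genes, 79 were expressed, at a median of 1016, led by Rps15 and Rps3a1.

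The last comparison sets the 2 libraries of the same treatment against each other, and its result is a difference between these libraries, not between conditions. Zona and growth genes were higher in replicate 2 and ribosomal protein genes were lower. Of 18 growth and zona genes tested, 14 were higher in replicate 2, with a median log2 ratio of 0.35, and 0 of 10000 random lists matched on expression had as high a median. In the exact binomial test, 11 were higher at an adjusted p under 0.05 over all genes tested and 13 when adjusted over the list alone, and none was lower.

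Zp2 was higher in replicate 2 by 0.49 on the log2 scale (counting SE 0.02, adjusted p = 6.1e-134, exact binomial test), Zp1 by 0.50 (SE 0.05, adjusted p = 4.9e-24, exact binomial test), Zp3 by 0.39 (SE 0.03, adjusted p = 4.4e-27, exact binomial test), Padi6 by 0.35 (SE 0.02) and Gdf9 by 0.36 (SE 0.05). Npm2, a histone chaperone of the egg and the member with the largest ratio, chosen after its value was seen, was higher by 1.00 (SE 0.09) with 388 and 815 counts. Bmp15, at -0.19 with 88 and 81 counts, did not pass the test. These SEs and p-values allow for counting noise only. Over all tested genes the counts spread more than that, with a chi-square of 3.55 per degree of freedom and a BCV of 7.31%. The p-values and the number of members past the test therefore overstate how firm the differences are.

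Of 79 ribosomal protein genes, 75 were lower in replicate 2, with a median of -0.12. An adjusted p under 0.05 was reached by 45 lower and 1 higher gene over all genes and by 55 and 1 when adjusted over the list alone, and 0 of 10000 random lists had as low a median. Most ribosomal protein genes have fractional counts, such as Rps15 with 4450.97 and 4214.4. These come from reads shared with other genes, so this small shift is uncertain. Immediate early genes had a median of -0.29, with 8 of 9 lower, 1 of them past the test with either adjustment, and 10 of 10000 random lists as low. Checkpoint and apoptosis genes had a median of -0.19, with 11 of 14 lower, 1 past the test over all genes and 3 when adjusted over the list alone, and 49 of 10000 random lists as low. PI3K-mTOR genes had a median of 0.11, with 10 of 14 higher, 2 higher and 1 lower past the test over all genes, 4 and 1 when adjusted over the list alone, and 96 of 10000 random lists as high. The medians of the remaining lists lay within the middle 95% of matched random lists. In all, 25 lists were compared, 22 of them fixed before the data were examined. The places among random lists are not adjusted for this number. The shifts of the checkpoint and PI3K-mTOR lists, with 49 and 96 of 10000, may therefore come from comparing many lists. Germ cell markers had a median of 0.06, with 3 members higher and 1 lower at an adjusted p under 0.05, and 5 and 1 when adjusted over the list alone. Oocyte transcription factors had a median of -0.03, with 1 higher and 1 lower, and 2 and 2 when adjusted over the list alone.

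**Figure D2:**
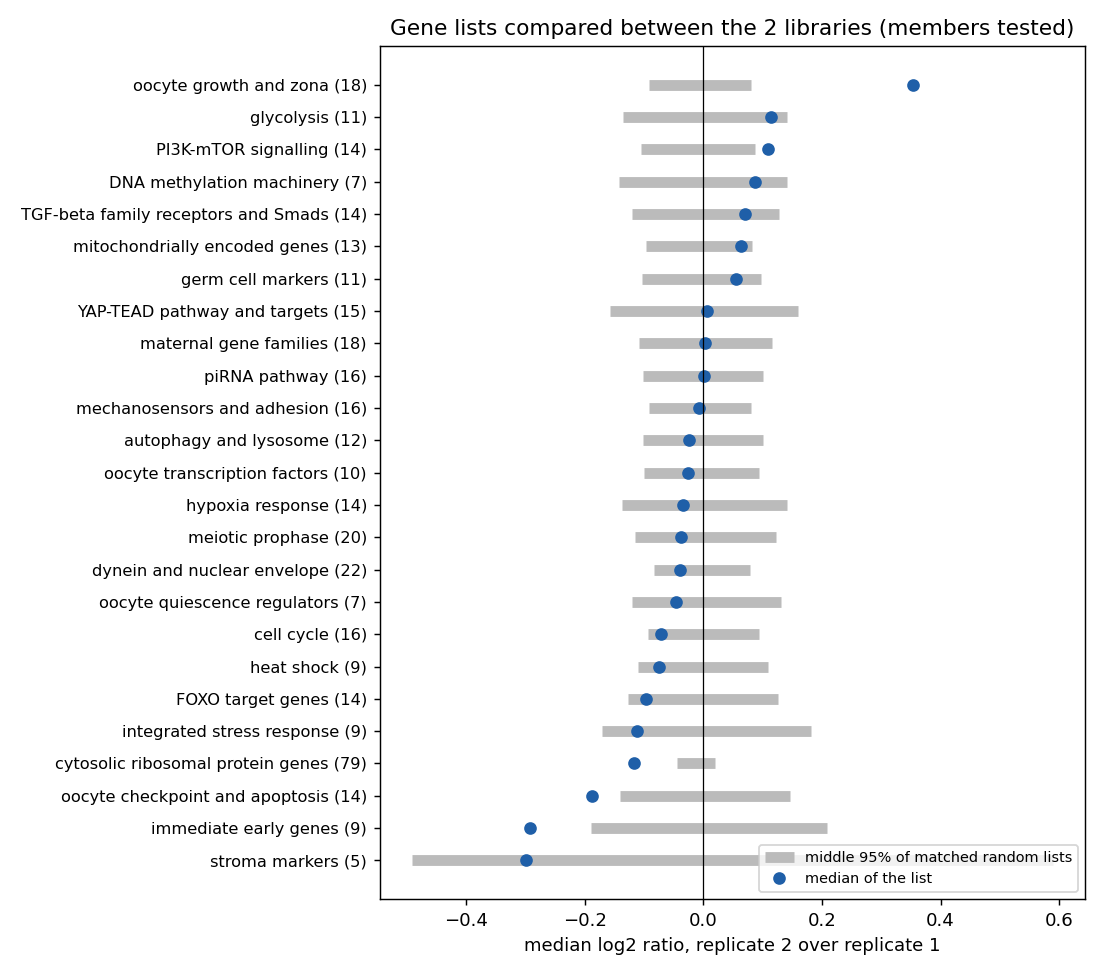
Median log2 ratio of replicate 2 over replicate 1 for each of 25 gene lists (points), with the middle 95% of 10000 random lists matched on expression (grey bars) and the number of members tested in parentheses. Oocyte growth and zona genes lie above their bar at 0.35 and ribosomal protein genes below theirs at -0.12.

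At 2-fold or more, 82 of 12182 genes were called, 52 higher and 30 lower in replicate 2. Among those with at least 10 CPM, the largest ratios upwards were Gm49369 at 2.17 (SE 0.34), Gm21982 at 1.41 (SE 0.29), the synaptic scaffold gene Pclo at 1.37 (SE 0.24), the oocyte cap-binding protein gene Eif4e1b at 1.36 (SE 0.23) and Gm13237 at 1.34 (SE 0.28). The largest downwards were Gm2423 at -1.52 (SE 0.22), Gemin4 at -1.37 (SE 0.19), Gm49037 at -1.28 (SE 0.30), Cox11 at -1.23 (SE 0.26) and the glycosyltransferase Galnt2 at -1.21 (SE 0.15). Gm13237, Gm2423 and Gm49037 are processed pseudogenes, and Gm49369, Gm21982, Gemin4, Cox11 and Galnt2 have fractional counts, which come from reads shared with other genes, so these are uncertain. Of the force-related genes, Ccn1 was at -0.80 in replicate 2 over replicate 1 (SE 0.20, adjusted p = 0.00206, exact binomial test), short of 2-fold, and Ccn2, at -0.69 with 28 and 18 counts, did not pass. The kinase gene Stk4 of the same list, chosen after its value was seen, was higher by 0.44 (SE 0.15), and the actins Actb and Actg1 were at -0.18 (SE 0.03) and -0.12 (SE 0.02), all 3 past the adjusted test and short of 2-fold. Actb and Actg1 also have fractional counts from reads shared with other genes, so their small shifts are uncertain. The binomial test allows for counting noise only, and with a preset BCV of 0.1 the number of called genes was 13.

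**Figure D3:**
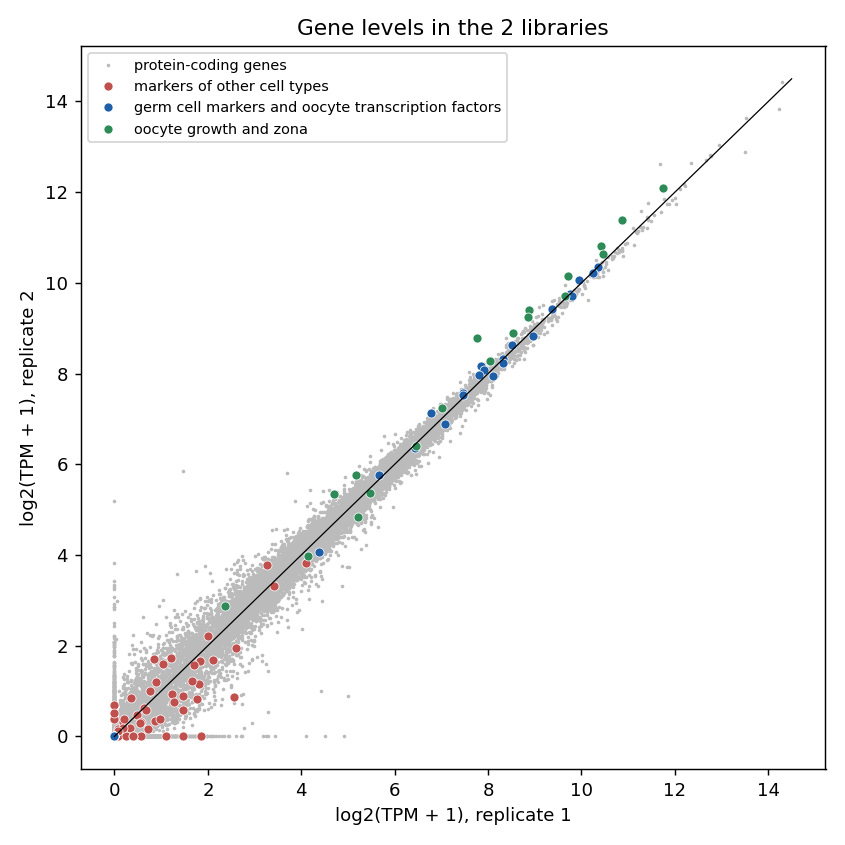
Levels of protein-coding genes as log2(TPM + 1) in replicate 1 (x axis) and replicate 2 (y axis), with the line of equality. Growth and zona genes (green) lie mostly above the line, germ cell markers and oocyte transcription factors (blue) scatter to both sides of it, and markers of other cell types (red) lie near the origin.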

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

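The length of the longest transcript and the summing of mitochondrial copies were chosen only after the results had been seen, and the other alternatives before. No paired analysis was possible because there is 1 group. The germ cell median stayed above every other cell type's median under all alternatives run, but its lead moved with the scale. With CPM the lead was 7.70 over granulosa, 7.11 over stroma, 7.64 over surface epithelium, 7.98 over endothelial and 8.53 over immune and erythroid markers, on the log2 scale. With a pseudocount of 0.1 it was 8.16, 8.72, 7.88, 9.62 and 11.27, and 9.35 over perivascular markers. Without mitochondrial genes in the totals it was 8.11 over immune and erythroid markers. With the longest transcript it was 7.38 over granulosa, 7.28 over surface epithelium and 8.08 over immune and erythroid markers. The lists of other cell types lie at or near the floor, where a lower pseudocount widens any lead by its construction. The medians of immune and erythroid markers were 0. The leads over these lists therefore only restate the germ cell level against the pseudocount. The lead of growth over quiescence genes reversed to -0.10 with CPM, and that of growth over meiotic genes was 2.40 with CPM and 3.75 with the longest transcript; CPM leaves out the division by gene length. With 1 library left out, the lead over quiescence genes ranged from 2.05 to 2.83. Spearman's rho was 0.951 without the filter. The number of genes that differed between the libraries was 82 with DESeq2 size factors, 81 with library totals and 82 with mitochondrial copies summed, against 211 without the filter, 955 without the fold minimum and 13 with a preset BCV of 0.1. Without adjustment, 2516 genes had p under 0.05. With DESeq2 size factors, library totals and no filter, each of the 25 lists compared between libraries stayed inside or outside the middle 95% of random lists as before, and the median of growth genes ranged from 0.35 to 0.37. At 5019462 and 5274338 counts, genes under 0.598 and 0.569 CPM cannot be told from absent ones.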

Other observations

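Of the tests below, the comparison of oocyte numbers and that of mitochondrial copies were chosen only after the result was seen, as were the 3 added lists' topics, the gene pairs and the choice of list differences to follow. Of 17 piRNA pathway genes, which silence transposons in germ cells, 16 were expressed, at a median TPM of 70.1, with Tdrd1 at 332 ± 7.26 and Piwil2 at 308 ± 1.18 above Piwil4 at 2.22 ± 0.0598 and Tdrd6 at 0 counts. The piRNA median lay above 99.6% of random lists of expressed genes. Of 17 TGF-beta family receptors and Smads, 14 were expressed, at a median of 15.8. Smad4 stood at 116 ± 4.19 and Tgfbr1 at 64.9 and 68.5, while Tgfbr2 had 0 and 2 counts. The median of this list lay above 92.7% of random lists of protein-coding genes. Among expressed genes, a background without unexpressed genes, its place was 15.4%. Of 32 genes of maternal families, 22 were expressed. The median of all 32 on the log2(TPM + 1) scale, taken over each gene's mean of the 2 libraries, was 2.27. The medians of the single libraries were 1.99 in replicate 1 and 2.76 in replicate 2, with an SD of 0.54. Nlrp4f stood at a TPM of 466 ± 2.14 and Zbed3 at 460 ± 6.61, above Oog4 at 1.14 ± 0.375, and Obox1 and Obox3 had 0 counts. Of 10000 random lists of protein-coding genes, 3660 had as high a median, and so had all 10000 lists of expressed genes, a background without unexpressed genes, of which this list holds 10.

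Pairs of genes were compared within each library. Among lactate dehydrogenase subunits, the TPM of Ldhb was 486 and 830 times that of Ldha (230 and 394 times in CPM), which had 32 and 20 counts. The paralogues Yap1 and Wwtr1 stood at ratios of 1.02 and 1.06 in TPM and 1.97 and 2.06 in CPM. The ion channel Trpm7 stood at 193 and 192 times Piezo1 (both 219 in CPM), whose counts were 7 and 8. Trp63, the guardian of the oocyte genome, stood at 3.65 and 4.19 times Trp53 in TPM and 7.56 and 8.69 times in CPM. Xist, which silences an X chromosome in female somatic cells, had 75 and 47 counts. The median level of 422 expressed X-linked genes was 0.984 and 0.962 times that of 11182 autosomal genes, and 39.96% of random autosomal sets of that size lay below.

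The growth and zona list was higher in replicate 2 by a median of 0.35 on the log2 scale. A bias by GC content and gene length, of the form that a regression on both removes, was argued against. After this correction the median was 0.36 and lay above 100% of matched random lists. Fewer oocytes among the sorted cells of replicate 1 are unlikely as the source. Germ cell markers and oocyte transcription factors had a joint median of -0.01 (-0.00657, SE of the median over the 21 genes 0.0448). This SE is a spread over genes, which are not replicates, and does not cover the spread between libraries. Sub1, Dynll1 and Stat3, among these 21, may also be expressed by other cells, which weakens this test. The 11 germ cell markers alone had a median of 0.06. A larger share of advanced oocytes in replicate 2 may contribute and stays open, because the separate list of maternal families gave no clear answer. Its median lay above 53.01% of random lists, with 9 of 18 members higher and 9 lower. At an adjusted p under 0.05 in the exact binomial test, 4 were higher and 1 lower. Oosp2, Oog1 and Nlrp4a were higher by 1.26, 1.43 and 1.49, with 20, 10.94 and 20 counts in replicate 1. They were named after their values were seen and are no separate support. The design names no biological difference between the libraries, so none from the design was tested.

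The ribosomal protein genes were lower in replicate 2 by a median of -0.12, and 75 of 79 went that way. A regression on GC content and gene length over all tested genes did not remove the difference. The median after this correction was -0.11 and 0 of 10000 random lists were as low. A bias of a form that this fit does not capture was not tested. GC content and length together explained 0.895% of the variance of the log2 ratios over 12177 genes. Most of these genes have fractional counts from reads shared with other genes. Whether this sharing adds to the shift was not tested, nor were other technical and biological explanations.

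Among 4 pairs of a mitochondrial gene and its chromosome 1 copy with enough counts in both parts, 3 differed between the libraries in opposite directions, such as mt-Co2 at 0.93 against -0.29 for its copy Gm28661. A candidate explanation is that reads were shared between near-identical copies in different proportions, and it stays open. It was taken to predict that sums of a gene and its copy differ by less than either part. Over the 4 pairs the largest difference of a sum was 0.153, for mt-Co1 and Gm29216. The smallest part differed by 0.135, also mt-Co1, and the largest by 0.93. That pair could not have met the prediction, because its parts moved the same way, at 0.135 and 0.40, and a sum lies between its parts. The comparison over all 4 pairs therefore cannot decide the explanation. In the 3 opposite pairs the sums differed by at most 0.09, which opposite signs partly build in. The copies of mt-Atp6, mt-Co2 and mt-Co3 in these pairs are 100% identical to the gene over 678, 681 and 783 bp. Reads within these stretches cannot be assigned to gene or copy by sequence. The opposite ratios of the parts are therefore no evidence that gene and copy moved apart. The limit to pairs with enough counts was set after a first run over all 7 pairs, where the largest difference of a sum was 0.33, for mt-Nd4l.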
